A study of Mus musculus with 12 samples.

How the data were processed

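RNA from primary mouse keratinocytes at day 0 and day 4 of a calcium shift was profiled in 12 libraries, 3 input and 3 anti-m6A immunoprecipitated libraries per day. Per the labels' protocols, polyadenylated RNA was broken by sonication, enriched with a commercial N6-methyladenosine antibody kit and made into libraries with a stranded kit. Per the submitters' processing notes, the tools were HISAT2 2.1.0 and DESeq2 1.18.1 and the genome build mm10. The peak caller and the test behind the methylation table are not given in the sources used here. Each library was placed in a group by its title.

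The files used were 2 peak lists, an expression table and a methylation table. None has a value per library, so library depth is unknown and no test across replicates was possible. Each peak list has an enrichment score, whose scaling the authors do not state, and an unadjusted p-value per peak, per the file headers. How the 3 replicates were joined into 1 list per day is not given in the sources used here. The expression table holds the authors' mean normalized count, a signal averaged over the compared libraries, with a log2 fold change, its standard error, a test statistic and an adjusted p-value, per the file headers, and its column names are those of DESeq2. The methylation table holds a log fold change treated here as a score, because its base is not stated in the deposited file, with a p-value and a false discovery rate per site. Both comparison tables list only genes or sites under 0.05, so a gene that is not listed was either not called or not tested. The number tested was derived from the adjusted p times its rank over the p.

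The header does not name the direction of either comparison. Expression changes were read as day 4 over day 0 because genes with peaks on a single day went that way, and methylation changes likewise from the peaks the sites overlap. Gene symbols were used as given, since the Ensembl identifier of 136 lines stands on another line too. Gene spans came from a RefSeq table of GRCm38.p6, the assembly of mm10, and over 99.9% of peaks in protein-coding genes lay inside their gene's span.

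Groups, tests, 15 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls at an adjusted p under 0.05 and a mean normalized count of at least 100, leaving out predicted genes. It added Pvt1, Myc, every m6A gene, and from each list up to 4 listed members with the largest change and up to 2 that go the other way. For sites it took the 10 largest finite gains and losses, those in Pvt1 and Myc and up to 4 per list, and for peaks those in Pvt1 and Myc and the 5 with the highest score per day. The lists hold 290 genes, 2 of them found under another symbol.

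Each list was tested with a two-sided Fisher's exact test of members higher against lower, relative to other genes of the expression table, with Benjamini-Hochberg adjustment over the lists. Lines of the table with identical values were counted once in these tests. Genes are the units, so these p-values describe the table and not the replicates. A count adjusted over the list alone needs p-values of genes outside the table and was not made. Where a 2 by 2 table held a 0, 0.5 was added to each cell for the odds ratio. Odds ratios have normal 95% intervals on the log scale. Permutation tests used 100000 permutations. Peaks were intersected with bedtools 2.31.1 on the same strand, with at least 1 bp in common. A gene's methylation change was the mean over its sites. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and a stratified analysis in statsmodels 0.14.6. On simulated data over the 7978 genes, 20 of 20 planted lists of 30 genes were found and 1 of 20 unplanted lists was called. Most fixed lists had fewer than 30 listed genes, and simulated directions were drawn independently per gene, so this rate does not carry over to them. The shortest lists could not pass: the 2 listed melanocyte markers were both higher, with an unadjusted Fisher's exact p of 0.500. Intervals of shares cover counting error over genes only.

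Alternatives were stricter p-values, a change of at least 2-fold, a mean of at least 100, other overlap rules, stricter peaks and other ways to count sites. The position of peaks within untranslated and coding regions and the DRACH motif, both planned, need an exon annotation and a genome and were not analysed here. Scores were used within a list, with an exception. After the data were seen, scores of the 2 lists were set against each other at the called sites, as a way to see what the scaling decides. No common scale of the 2 lists is given in the sources used here, so this count is not a measure of change.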

Results

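Primary keratinocytes from newborn mouse epidermis, grown on feeder fibroblasts that mitomycin C had stopped from dividing, were compared before and after differentiation by a calcium shift, the standard switch that makes cultured keratinocytes leave the proliferating state. Polyadenylated RNA was taken at day 0 (undifferentiated) and day 4 (differentiated). Part of the fragmented RNA was pulled down with an antibody against N6-methyladenosine (m6A), the internal methylation of mRNA, and part was sequenced directly as input. There were 12 libraries: 3 day 0 input, 3 day 4 input, 3 day 0 immunoprecipitated and 3 day 4 immunoprecipitated. The values used were the authors' own tables and peak lists, which carry no column per library, so the depth of each library is unknown here. The labels do not say whether replicates came from separate animals, so the p-values in these tables measure only the spread between these samples, which may be technical.

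The question of the expression comparison was which transcripts change as epidermal progenitors differentiate. Clusterin (Clu), a secreted chaperone, was 63.8-fold higher at day 4 in the authors' deposited table, with an SE of 0.10 on the log2 scale, and the formin Fhod3 had the largest rise among genes with a mean normalized count of at least 100 (log2 fold change 7.99, SE 0.67). Other leading rises in the authors' deposited table were the phospholipid transporter Atp10b (6.09, SE 0.38), the amino acid transporter Slc6a14 (5.86, SE 0.25), the kinesin Kif26b (5.52, SE 0.35), Ctla2a (5.22, SE 0.13) and the prostaglandin D synthase Hpgds (5.11, SE 0.15). Log2 fold changes of the alarmin Il33 (5.09), Tm4sf1 (5.08), the junction protein Cgnl1 (5.06), the kinase Nuak1 (4.79) and the growth factor Tgfb3 (4.76) closed the 12 largest rises among genes of that level in the authors' deposited table. At the same minimum level, the largest falls in the authors' deposited table were cystathionine gamma-lyase Cth (-5.83, SE 0.24), which makes cysteine, and the mitochondrial folate enzyme Aldh1l2 (-5.82, SE 0.19). They were followed in the authors' deposited table by the connexin Gjb2 (-5.20), the stress pseudokinase Trib3 (-4.71), the amino acid transporters Slc7a11 (-4.65), Slc7a3 (-4.63) and Slc7a5 (-4.57), and the branched-chain aminotransferase Bcat1 (-4.44). Vwa2 (-4.32), Nr1h5 (-4.29), Phyhd1 (-4.16) and the neuregulin Nrg2 (-3.93) completed the 12 largest falls at that level in the authors' deposited table, and some genes of lower level had larger changes.

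In total, the authors' deposited table holds 7978 genes, all at an adjusted p of at most 0.0500 by DESeq2, of which 4040 were higher and 3938 lower at day 4 (50.6% higher). The adjustment itself implies that 14924 genes were tested, so the table holds 53.5% of them. The majority depended on the genes kept, with 49.5% higher at an adjusted p under 0.01, 53.3% among genes changed at least 2-fold and 46.3% among the 6404 genes with a mean normalized count of at least 100. The median SE of the log2 fold change was 0.14 in the authors' deposited table. With a change of at least 2-fold required, 3164 genes remained, 1686 higher and 1478 lower. Genes with low means were common, 1574 of them under a mean normalized count of 100 and 447 under 10.

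Genes of the basal layer, where epidermal progenitors sit, went both ways. Of 17 basal members, 6 were higher, 9 lower and 2 not listed in the table. Krt15 had a log2 fold change of 4.57 (SE 0.11) and the transcription factor Sox9 1.89 (SE 0.14) in the authors' deposited table, against -1.38 (SE 0.10) for the integrin Itga3 and -2.25 (SE 0.60, mean normalized count 11.8) for Itga2. The basal keratins Krt14 (1.06, SE 0.11) and Krt5 (0.96, SE 0.09), chosen after their values were seen, were also higher in the authors' deposited table. The balance of directions in the list did not differ detectably from that among other genes of the table (odds ratio of being higher 0.651, 95% interval 0.231 to 1.83, two-sided Fisher's exact test, Benjamini-Hochberg p over 15 lists = 0.674). Among the 5 members changed at least 2-fold the log2 odds ratio turned from -0.62 to 0.40.

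Early differentiation genes of the spinous layer were also mixed, with 9 of 17 higher, 7 lower and 1 not listed (odds ratio 1.26, 95% interval 0.468 to 3.38, adjusted p = 0.927, Fisher's exact test). Among the 9 members changed at least 2-fold the log2 odds ratio turned from 0.33 to -0.51. Krt1, a keratin of the spinous layer, had a log2 fold change of 5.10 in the authors' deposited table, but with a mean normalized count of 2.65 and an SE of 1.54. The repressor Prdm1 rose (1.48, SE 0.14), whereas Ovol1 (-2.21, SE 0.17) and Krtdap (-1.73, SE 0.11) fell in the authors' deposited table.

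Genes of the cornified envelope, the cross-linked shell of the outermost layer, numbered 53, of which 15 were higher and 27 lower. The other 11 were not listed, except that Sprr2a1 and Sprr2a2, which are both in the table, were counted as a single higher gene. The late cornified envelope gene Lce1f (3.72, SE 0.17) and involucrin, Ivl (3.67, SE 0.12), were among the higher genes in the authors' deposited table. Lce3b (-5.00, SE 0.73), Rptn (-4.45, SE 0.55) and Flg2 (-4.44, SE 1.66) were among the lower, with mean normalized counts of 23.6, 77.2 and 1.88 in the authors' deposited table. The list as a whole did not pass the test (odds ratio 0.541, 95% interval 0.287 to 1.02, adjusted p = 0.157, Fisher's exact test), and its log2 odds ratio turned from -0.89 to 0.34 among the 23 members with a mean normalized count of at least 100 (adjusted p = 1). Sprr and Lce genes lie in families of near-identical copies, and Sprr2a1 and Sprr2a2 carry identical values in the table, so single members of these families are uncertain.

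Barrier lipid genes, which make and process ceramides and other lipids of the outer layer, were higher for 5 of 25 members, lower for 13 and not listed for 7. Pnpla1 (-4.01, SE 0.54), Acer1 (-3.70, SE 1.23), Degs2 (-3.35, SE 0.42) and Cyp4f39 (-2.56, SE 0.36) fell in the authors' deposited table, and Lipm (1.64, SE 0.23) and the fatty acid transporter Slc27a4 (0.91, SE 0.11) rose. The list did not pass over all its listed genes (odds ratio 0.375, 95% interval 0.134 to 1.05, adjusted p = 0.157, Fisher's exact test), and passed among genes changed at least 2-fold (adjusted p = 0.0400, 10 genes, Fisher's exact test). With a mean normalized count of at least 100 the log2 odds ratio was -0.46, against -1.42 for all listed members (adjusted p = 1, 13 genes, Fisher's exact test).

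Cell cycle genes were lower at day 4 in all 31 of 31 members, with a median log2 fold change of -2.13. Cyclin D1 (Ccnd1, -3.37, SE 0.11), cyclin A2 (Ccna2, -3.01, SE 0.13), topoisomerase Top2a (-2.88, SE 0.12) and cyclin B1 (Ccnb1, -2.88, SE 0.15) led the list in the authors' deposited table. The test against other genes of the table gave an odds ratio of 0.0154 (95% interval 0.000941 to 0.252, adjusted p = 4.6e-09, Fisher's exact test). Genes of Myc and of ribosome biogenesis were lower in 19 of 21 members, higher in 1 and not listed in 1 (odds ratio 0.0512, 95% interval 0.00685 to 0.383, adjusted p = 1.3e-04, Fisher's exact test). Ornithine decarboxylase Odc1 (-2.17, SE 0.15), nucleolin Ncl (-2.04, SE 0.10), spermidine synthase Srm (-1.83, SE 0.13) and the nucleolar protein Nop56 (-1.73, SE 0.13) fell in the authors' deposited table. The exception was lactate dehydrogenase Ldha (0.59, SE 0.08), a glycolytic enzyme, in the authors' deposited table.

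Of 20 genes that write, erase or read m6A, 9 were listed and all 9 were lower at day 4, while 11 were not listed. The methyltransferase subunits Mettl3 (-0.38, SE 0.12), Mettl14 (-0.50, SE 0.14) and Zc3h13 (-0.51, SE 0.16) and the separate methyltransferase Mettl16 (-0.85, SE 0.12) fell by modest amounts in the authors' deposited table. Larger falls were those of the reader genes Igf2bp3 (-1.55, SE 0.11) and Igf2bp1 (-1.42, SE 0.14), with Igf2bp2 (-0.56, SE 0.09), Ythdc2 (-0.88, SE 0.15) and Hnrnpa2b1 (-0.40, SE 0.10) beside them in the authors' deposited table. Wtap, Virma, Rbm15, Rbm15b, Cbll1, Fto, Alkbh5, Ythdf1, Ythdf2, Ythdf3 and Ythdc1 were not listed in the table. The list passed the test (odds ratio 0.0513, 95% interval 0.00298 to 0.882, adjusted p = 0.00875, Fisher's exact test). The call ended among genes changed at least 2-fold, where 2 members remained (adjusted p = 0.474, Fisher's exact test).

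The remaining lists did not pass. Desmosome and tight junction genes were higher in 10 of 18 members and lower in 3 (adjusted p = 0.198, Fisher's exact test), led in the authors' deposited table by Cldn23 (4.09, SE 0.19), Pkp2 (1.31, SE 0.12) and Cldn4 (1.21, SE 0.14), with Cldn7 (-0.58, SE 0.13) and Dsc3 (-0.51, SE 0.13) going the other way. Wound and stress genes were higher in 8 of 15 and lower in 4 (adjusted p = 0.646, Fisher's exact test). Among them Slpi (-2.33, SE 0.17) and Lcn2 (-1.74, SE 0.13) fell and S100a9 (2.81, SE 0.69, mean normalized count 15.1) rose in the authors' deposited table. Higher members with larger means, chosen after their values were seen, were Il1a (1.09, SE 0.13), Krt6b (0.87, SE 0.10) and Krt6a (0.80, SE 0.09) in the authors' deposited table. Krt16 (0.80, SE 0.13) and Krt17 (0.50, SE 0.10) were also higher in the authors' deposited table. In the Notch list 4 of 12 were higher and 2 lower (adjusted p = 0.859, Fisher's exact test), the ligands going apart in the authors' deposited table, with Jag2 at -2.19 (SE 0.15), Dll1 at 1.84 (SE 0.11) and Jag1 at 1.27 (SE 0.15). AP-1 and immediate early genes had 3 of 10 higher and 2 lower (adjusted p = 1, Fisher's exact test), including Fos at -1.84 (SE 0.16) and Fosb at 3.91 (SE 0.51, mean normalized count 26.5) in the authors' deposited table. Interferon response genes were higher in 6 of 15 and lower in 0 (adjusted p = 0.117, Fisher's exact test), at low levels, such as Rsad2 (7.12, mean normalized count 8.61) in the authors' deposited table. In total 3 of 15 lists passed.

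Markers of other cell types were also listed. Of 17 fibroblast and feeder markers, 5 were higher, 1 lower and 11 not listed (adjusted p = 0.410, Fisher's exact test). Values in the authors' deposited table were 4.58 (SE 0.38) for Col5a1, 3.66 (SE 0.22) for Postn, 2.97 (SE 0.12) for the smooth muscle actin Acta2 and -2.07 (SE 0.24) for Col6a1. Melanocyte markers had 2 of 8 higher (adjusted p = 0.682, Fisher's exact test), Mitf (1.65, SE 0.21) and Kit (6.14, SE 1.41, mean normalized count 4.74) in the authors' deposited table. Of 11 immune and endothelial markers, 2 were higher and 1 lower (adjusted p = 1, Fisher's exact test), with Cd68 at -1.92 (SE 0.23) and Pecam1 at 2.32 (SE 0.94, mean normalized count 5.30) in the authors' deposited table.

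**Figure D1:**
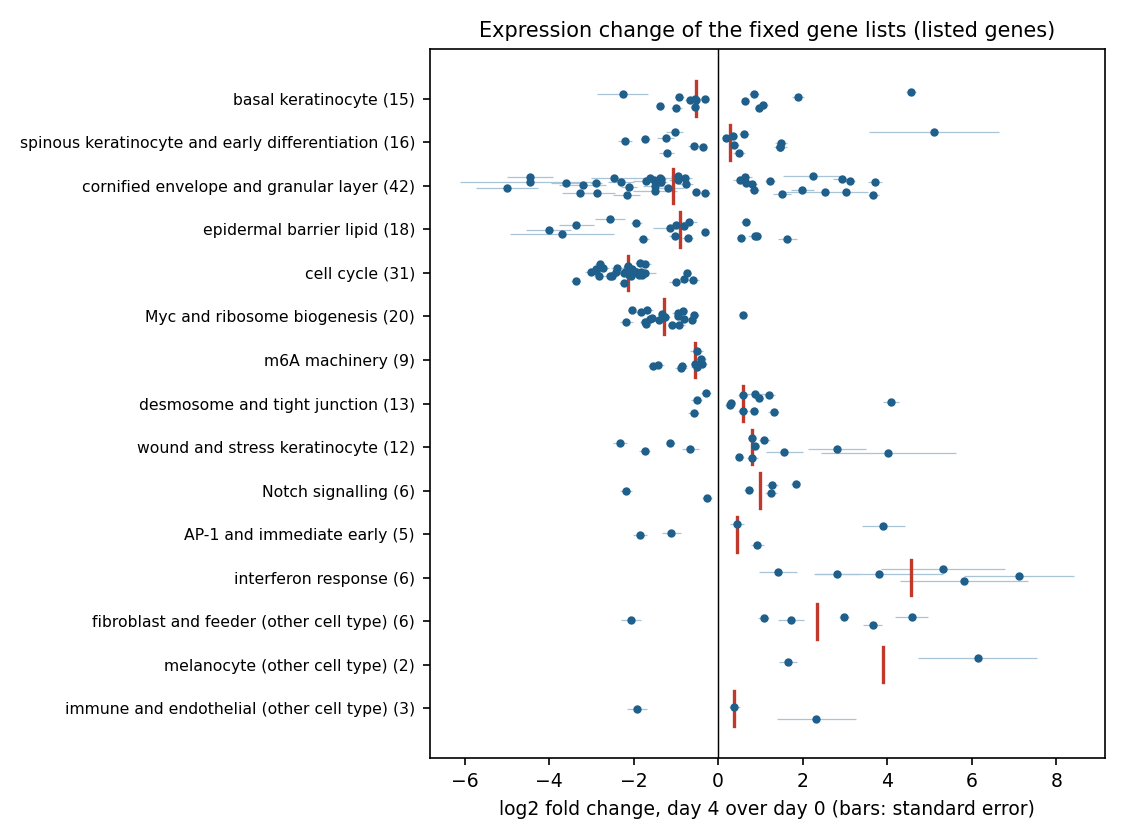
Log2 fold change at day 4 over day 0 (horizontal axis) of each gene of the 15 fixed lists that the authors' deposited table holds, as points with the authors' standard errors as bars. Red lines are list medians and numbers in brackets count listed genes, with identical lines counted once. All 31 cell cycle genes and all 9 listed m6A genes lie left of 0, and the basal, spinous and cornified lists spread to both sides.

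The peak lists ask where m6A lay on each day. Per the authors' list, day 0 had 19920 peaks in 7379 genes and day 4 had 18423 peaks in 6945 genes. Of these genes, 6332 had a peak on both days, 1047 at day 0 only and 613 at day 4 only. A same-strand overlap of at least 1 bp joined 70.2% of day 0 peaks to a day 4 peak, and 78.9% of day 4 peaks to a day 0 peak. The highest enrichment scores, which are the authors' own values, were in Cops2, Herc2, Usp34, Phip and Fbxo11 at day 0 and in Herc2, Arf2, Disp1, Pde4b and Phip at day 4. The Cops2 peak lay on chromosome 2 from 125831835 to 125833765 (mm10, score 2915) and the day 0 Herc2 peak on chromosome 7 from 56230899 to 56231448 (score 2666). Peaks lay more often near annotated 3′ ends than near 5′ ends of genes. Distances were counted along the genome with introns and without a background of transcript positions, so this does not show enrichment at 3′ ends. Among peaks in protein-coding RefSeq genes, 26.0% at day 0 and 28.0% at day 4 lay within 1000 bp of the annotated 3′ end, against 5.57% and 7.27% within 1000 bp of the 5′ end. Median span was 198 bp at day 0 and 150 bp at day 4. Only 3 day 0 and 18 day 4 peaks had an unadjusted p above 0.05.

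Pvt1, the long noncoding RNA in the title of the study, and its neighbour Myc were both lower at day 4. The log2 fold change was -0.91 (SE 0.18, DESeq2 adjusted p = 2.5e-06) for Pvt1 and -0.83 (SE 0.11, DESeq2 adjusted p = 1.8e-14) for Myc in the authors' deposited table. Pvt1 spans chromosome 15 from 62037986 to 62260215 in mm10. It had 1 peak at day 0, from 62107280 to 62107329 (score 74.3, the authors' unadjusted p = 1.4e-07), and none listed at day 4. That peak lies inside a site from 62038086 to 62107428, whose ends may span introns, with a log fold change in methylation of -1.19 (false discovery rate 0.0381) in the authors' deposited table. The site would not pass a false discovery rate under 0.01. Pvt1 had a mean normalized count of 153 and fell in expression, so the lack of a listed day 4 peak need not be a loss of methylation. Myc, from 61985341 to 61990361, had 3 peaks at day 0. At day 4 the outer peaks were listed at the same coordinates, and the middle peak was listed in 2 parts, with the authors' unadjusted p = 0.589 and 2.2e-04. At an unadjusted p under 1e-5, a limit chosen after the data were seen, Myc had 3 peaks at day 0 and 2 at day 4. The peak near its 3′ end, from 61989512 to 61990211, had the highest score of the gene within each list. No site in Myc was listed as differentially methylated.

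**Figure D2:**
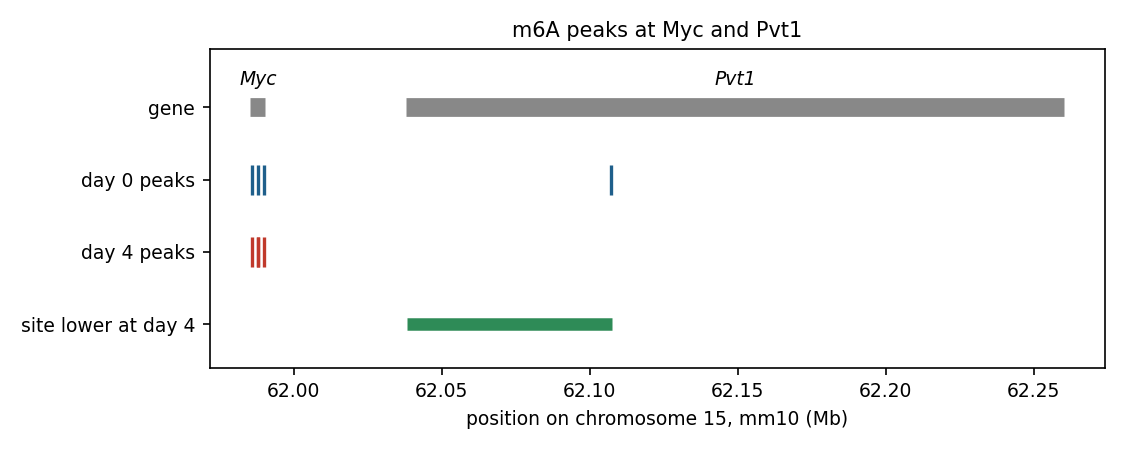
Map of Myc and Pvt1 on chromosome 15 (mm10, horizontal axis in Mb), with gene spans in grey, centres of the authors' peaks at day 0 (blue) and day 4 (red), and the site with lower methylation at day 4 (green). Pvt1 has 1 peak at day 0 and none listed at day 4, while Myc has peaks on both days.

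The methylation comparison asks which sites gain or lose m6A as the cells differentiate. The largest gains in the authors' deposited table were at Cnn3 (log fold change 6.83), Phlda3 (6.82), Pax2 (6.64), the heat shock gene Hspa1a (6.54), the growth factor receptor Egfr (6.26), Flad1 (6.22), Capzb (6.16), Timp2 (6.13), Zfp598 (6.08) and Mvd (5.98). The largest losses in the authors' deposited table were at Snn (-8.08), Mul1 (-5.90), Rbbp8 (-5.46), Setd7 (-5.21), Arpp19 (-5.16), Clcn5 (-5.07), Zfp322a (-4.96), Lace1 (-4.96), Gid4 (-4.95) and Asrgl1 (-4.91). Some of these sites were called near the limit, such as Timp2 (false discovery rate 0.0451), Mul1 (0.0415) and Rbbp8 (0.0458). Others lay far below it, such as Cnn3 (6.0e-05) and Snn (1.1e-04). The log base of the fold changes is not given in the sources used here. The gain at Cnn3 lay on chromosome 3 from 121426541 to 121426639 and the loss at Snn on chromosome 16 from 11073903 to 11073952 (mm10). A further 152 gains and 30 losses had infinite values and stood outside this ranking.

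Gains outnumbered losses, with 1763 gains and 798 losses among 2561 sites (68.8% gains) in the authors' deposited table. The adjustment implies 36796 sites tested, so 6.96% were called. Of the called sites, 583 overlapped no listed peak on either day, 495 gains (28.1% of gains) and 88 losses (11.0% of losses), and 138 of the 152 infinite gains were among them. At a false discovery rate under 0.01, 1362 sites remained. The sites lay in 2091 genes, 1352 with gains only, 653 with losses only and 86 with both. The median finite change was 1.82 for gains and -0.83 for losses in the authors' deposited table. The sign was read from the peak lists: sites that overlapped only a day 4 peak were gains in 414 cases and losses in 5, and those that overlapped only a day 0 peak were gains in 29 and losses in 90. How the authors scaled the days to each other is not given in the sources used here, and the split between gains and losses rests on that scaling. Of 941 called sites with a single peak in each list, 550 were gains by the table (58.4%), but 394 had the higher unscaled peak score at day 4 (41.9%, exact binomial 95% interval 38.7 to 45.1). The majority thus had the higher score at day 0. The scores have no stated common scale, so this count, chosen after the data were seen, measures no change in methylation.

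By fixed list, the site with the smallest false discovery rate among those named was in the AP-1 gene Jund, on chromosome 8 from 70699972 to 70700269, a gain with a log fold change of 3.44 (false discovery rate 2.2e-130) in the authors' deposited table. Gains at Junb (2.14), Fos (2.53) and Ier3 (3.16) stood beside it in the authors' deposited table. In the cornified list, Sprr1b (4.52), Lce3c (2.72), Crct1 (2.60) and Asprv1 (2.51) had gains in the authors' deposited table, and among basal genes Col7a1 (4.06) and Krt15 (2.93). Spinous genes with gains included Sbsn (2.95), Klf4 (2.36), Dmkn (1.91) and Prdm1 (1.76) in the authors' deposited table. Losses named by the rule in these lists were at the barrier lipid gene Abca12 (-1.31, false discovery rate 9.2e-25), which also had a gain (2.58, false discovery rate 0.00529), Maml1 (-0.59) and Fn1 (-2.98) in the authors' deposited table. Sbsn had 1 gain and 1 loss. Cell cycle genes with gains included Cdc20 (4.29, false discovery rate 0.0328), Tpx2 (3.85, false discovery rate 0.0454), Top2a (2.45) and Ccnd1 (2.09) in the authors' deposited table. These cell cycle genes all fell in expression and had fewer listed peaks at day 4. Peaks went from 1 to none for Cdc20, 4 to 2 for Tpx2, 5 to 1 for Top2a and 6 to 2 for Ccnd1. In the cornified list, Lce3c also had 1 peak at day 0 and none listed at day 4, whereas Crct1 had none at day 0 and 1 at day 4. Counting each gene once by its mean change, the cornified list had 14 genes with a gain and 0 with a loss, the m6A list 3 and 5, and the cell cycle list 5 and 2. None of the 12 lists with a site passed a test against other genes of the table. The smallest adjusted p was 0.0870, for the cornified list (odds ratio 13.7, 95% interval 0.815 to 230, two-sided Fisher's exact test), in a test chosen after the data were seen.

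Methylation and expression changes were set side by side for 1421 of the 1423 genes in both tables, the other 2 having infinite changes in both directions and so no mean. Genes with a gain of methylation were higher in expression in 540 cases and lower in 464 (53.8% higher), and genes with a loss were higher in 178 and lower in 239 (42.7% higher). The odds ratio was 1.56 (95% interval 1.24 to 1.97, two-sided Fisher's exact test p = 1.5e-04). Among genes changed at least 2-fold in expression its log2 value was 1.46, against 0.64 for all. Across genes, Spearman's rho was 0.00055 over 1301 genes with finite values (permutation p = 0.984), but -0.20 among 901 genes with gains and -0.18 among 400 with losses (Benjamini-Hochberg adjusted permutation p over 3 correlations = 3e-05 and 4.8e-04). Genes are not independent replicates in these tests, and whether the methylation values were corrected for expression is not given in the sources used here. If they were taken relative to input, the same input libraries enter both changes. Noise in those libraries could then make the correlations negative by itself, which was not tested. In 3 strata of mean expression, from low to high, the odds ratio was 1.93 (95% interval 1.33 to 2.79), 1.49 (1.00 to 2.21) and 1.07 (0.637 to 1.80). A difference between strata was not detected (Breslow-Day p = 0.189 across genes, n = 1421, added after the data were seen), and the Mantel-Haenszel odds ratio over them was 1.55 (95% interval 1.22 to 1.96).

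**Figure D3:**
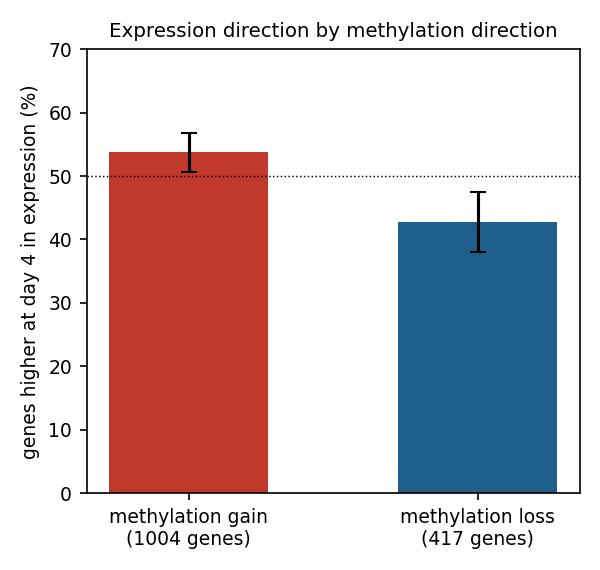
Percent of genes higher in expression at day 4 (vertical axis) among 1004 genes with a methylation gain and 417 with a loss; bars are Wilson 95% intervals over genes and the dotted line marks 50%. The values are 53.8% and 42.7%.

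A peak can be called only where its transcript is expressed, so the day on which a gene has a peak depends on its expression change. Of 797 listed genes with peaks at day 0 only, 765 were lower at day 4 (96.0%), and of 497 with peaks at day 4 only, 466 were higher (93.8%). Genes with an overlapping peak on both days were higher in 1962 cases and lower in 1956. These counts served to read the direction of the expression table, which its header does not name, and are not a result on methylation.

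The expression change of genes with and without a peak was compared next. The median log2 fold change was -0.38 for 4748 genes with a day 0 peak and 0.68 for 3230 without, but a peak called at day 0 needs expression at day 0, which favours genes lower at day 4. With a peak on either day as the criterion, the medians were -0.30 for 5245 genes and 0.56 for 2733, a difference of -0.86 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The median mean normalized count was 861 in genes with a peak on either day and 83.2 in those without, so the sets also differ in expression level. Genes outside the table are not part of this comparison.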

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

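The tests of peaks at a p under 1e-5 and of unscaled scores were added after the data were seen. Of 82 alternatives, 61 were classed as the same, 14 as moved and 5 as reversed, and 1 gained and 1 lost its call. The 5 reversed were gene lists whose log2 odds ratio changed sign, and in none of them was either value past the threshold. Counts and percentages were classed only as the same or moved, so a majority that turned stands among the moved. Counts were classed as the same within a set ratio of the main count, not by an interval. The same class also holds lists that passed in neither setting. It holds tests of day-specific peaks too, which had served to read the direction of the expression changes. The number classed as the same is therefore not a number of calls that held. The percent of genes higher went from 50.6% to 49.5% at an adjusted p under 0.01 and to 46.3% with a mean of at least 100. The share of called sites with the higher unscaled score at day 4 lay under 50%. This is not a share of gains, and the scores have no stated common scale. The cause of such changes was not tested unless a smaller set of genes is named. A change of at least 2-fold left 3164 genes. Day 0 and day 4 peak sharing was 52.4% and 56.6% with 50% reciprocal overlap, 74.1% and 81.4% among the 50% of peaks with the smallest p, and 72.5% and 79.8% at a p under 1e-5. At a false discovery rate under 0.01, 1362 sites remained with 72.5% gains, and gains were 83.6% among log fold changes of at least 1. By unscaled scores 41.9% of 941 sites were higher at day 4. Among genes changed at least 2-fold, log2 odds ratios turned to 0.40 for the basal list, -0.51 for the spinous list, -1.18 for AP-1 genes and -0.18 for immune and endothelial genes, and with a mean of at least 100 to 0.34 for the cornified list. At least 2-fold, the barrier lipid list gained its call (-3.36) and the m6A list lost it (-2.51, 2 genes left).

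No paired analysis was possible because the tables hold no values per library. For the same reason another normalization or tool, the replicate block and leaving out a replicate were not run, and peak position and DRACH alternatives were not run for want of a genome and exon annotation. Depth is unknown, so genes with a mean under 10 carry the least certain changes.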

Other observations

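The tests of peak score were chosen after the result was seen. The amino acid response list was written after the 12 named falls were seen and leaves their members out. It also leaves out Mthfd2 and Vars, which are not among the 12 but had been seen as well. The values of its own genes had not been seen, and Stc2 among them, with a mean normalized count of 68.5, had a log2 fold change of -6.28 (SE 0.62) in the authors' deposited table. The list held 38 genes that amino acid shortage and the factor Atf4 are known to raise, and 37 were in the table, 36 of them lower at day 4. In the authors' deposited table the log2 fold change was -3.74 (SE 0.18) for the proline enzyme Pycr1, -3.35 (SE 0.11) for Aldh18a1, -3.24 (SE 0.14) for the serine enzyme Shmt2 and -1.63 (SE 0.10) for Atf4 itself. Asparagine synthetase Asns was 8.02-fold lower in the authors' deposited table, these examples being chosen after their values were seen. Genes for tRNA synthetases fell too in the authors' deposited table, such as Eprs (-2.14), Gars (-1.86) and Lars (-1.85). Nupr1 was the exception at 0.92 (SE 0.14) in the authors' deposited table.

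A hypothesis for the 3 amino acid transporters and the folate enzyme Aldh1l2 among the 12 named falls is that amino acid response genes fell as a set. The odds ratio of being higher, against other genes of the table, was 0.0269 (95% interval 0.00369 to 0.196, two-sided Fisher's exact test p = 1.8e-10), with a median of -1.68. A general fall of abundant transcripts is argued against, because 0% of 10000 random lists matched on mean expression had a median as low. Genes drawn at random need not change together, so this does not tell the list apart from other sets that fell. The cell cycle list (31 of 31 lower, median -2.13) and the Myc and ribosome list (19 lower, 1 higher, median -1.29) fell as well. A change of medium between days could give the falls of the amino acid response list. It is confounded with day in this design and stays open beside differentiation itself.

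Gains of methylation outnumbered losses, 1763 to 798, in the authors' deposited table, but by unscaled peak scores 41.9% of 941 called sites with a single peak in each list were higher at day 4, against 58.4% gains among them by the table. A candidate explanation is a less specific immunoprecipitation at day 4, which would flatten strong peaks against weak ones. Within the day 4 list, gains lay at lower scores than losses, with medians of 15.1 (1036 sites) and 39.4 (447 sites), a difference in median log2 score of -1.38 (permutation p = 1e-05, the smallest possible). The same order held within the day 0 list, with medians of 12.6 (628 sites) and 70.7 (556 sites), a difference of -2.49 (permutation p = 1e-05). Both orders also follow where weak sites gain for another reason, so the test does not favour this explanation over others. The scaling between days stays open, as does a true rise at day 4.

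Gains lay within 1000 bp of a gene's 5′ end in 14.6% of 1682 sites, against 3.20% of 750 losses (odds ratio 5.16, 95% interval 3.36 to 7.92, Fisher's exact test p = 1.7e-19). Gains also lay more often within 1000 bp of the 3′ end, 33.7% against 18.1% (odds ratio 2.29, 95% interval 1.85 to 2.83, Fisher's exact test p = 1.4e-15). Without stratification, the pattern is thus not particular to 5′ ends. The 3′ excess was not stratified, so whether it holds at equal gene length or span is not known. Genes with gains were shorter, with a median length of 18039 bp against 36431.5 bp for losses. Median spans over all called sites were 250 bp for gains and 672 bp for losses. For the 5′ end, gene length as the whole cause is argued against by a Mantel-Haenszel odds ratio of 3.63 over 5 strata of length (95% interval 2.33 to 5.64), although the longest stratum alone gave 1.66 (0.481 to 5.76). Sites drawn across long introns, as the whole cause, are argued against by an odds ratio of 3.91 among sites of at most 1000 bp (95% interval 2.46 to 6.20). Sites of that span may still cross short introns. Peak strength as the whole cause is argued against by 4.62 over 4 strata of day 4 score (2.61 to 8.16), against 5.40 unstratified, and by 4.56 over 4 strata of day 0 score (2.50 to 8.32), against 6.18. Gene length, span and peak strength were taken one at a time, so their joint effect was not tested. A change at gene ends with differentiation stays open and was not tested.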
